A study of Mus musculus with 9 samples.

How the data were processed

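Gene expression was measured on 9 Affymetrix oligonucleotide arrays of the MG-U74v2 series, which come as 3 complementary designs, A, B and C, each with its own probe sets. Per the labels, every array carried RNA of GFP-positive cells sorted from the retinas of pups that express GFP under the endothelial Tie2 promoter and that had been injected with APB5, a neutralizing antibody against the receptor PDGFRb. Each design was hybridised in 3 replicates. Per the labels' protocols, retinas were pooled and dissociated with papain in several incubations at body temperature, dead cells were marked with propidium iodide, and the RNA was amplified and biotin-labelled before hybridisation. The labels do not say whether the replicates came from separate pools of animals, so every spread given here is the spread between arrays, which may be technical.

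The deposited values are linear intensities, 1 per probe set and array, in a separate table for each design. The summary algorithm, software and scaling are not given in the sources used here. The medians of the 3 arrays of a design were close (43.6, 44.2 and 44.3 on design A), no value was negative, and 7 values were exactly 0 and took the smallest positive value of their array before logarithms. No detection calls were used here, and Affymetrix control probe sets were not among the probe sets analysed. The number of arrays limits the precision, and no counting error can be given for intensities.

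Probe sets were named from the platform annotation, with symbols checked through Entrez identifiers against RefSeq for GRCm38.p6. Of 36701 probe sets, 29131 had 1 gene symbol, 724 had several and 6846 were unnamed here. Only probe sets with 1 symbol entered the gene-level comparisons, which covered 15964 genes. No coordinates are given, since the build behind the probe sets is not given in the sources used here.

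All arrays belong to 1 condition, so no contrast between treated and untreated animals was made, and no count or variance model was fitted. The comparisons are those the arrays allow. The position of each probe set was its percentile among all probe sets of its array, from 0 to 100, averaged over the replicates, and the probe sets of a gene on a design were averaged. For the SD of a list mean, and where a replicate was left out, arrays of equal number on the 3 designs were taken as 1 replicate, although the labels do not say that they share an RNA sample. Over all 36 ways to match the numbers, the SD of the pan-endothelial mean ranged from 0.109 to 1.08 percentile points, and that of any list reached at most 2.09. The tests against random lists use means over all arrays and do not depend on this matching. Because probe sets differ in hybridisation efficiency, an order of single genes by position reflects probes as well as transcripts, and it was used only to choose which list members to name. The tests are on lists, and 24 gene lists fixed before the data were examined were compared, each by its mean percentile, with 10000 random lists that held as many gene values from each design. A gene on several designs counted once per design, so the 23 measured pan-endothelial genes gave 34 values. Random lists were drawn on each design separately, so the values of 1 gene were treated as if from different genes. On design A alone, each gene counted once. The comparison is a two-sided permutation test over genes, which are not replicates, and it was adjusted by the Benjamini-Hochberg method over the 24 lists. The pan-endothelial list was compared with 9 lists of other cell types and with a list of genes specific to unrelated tissues (liver, pancreas, testis, pituitary and others, called tissue-foreign below) by 100000 permutations of list membership within design. Those permutations also counted a gene once per design. Blood cell lists were included because Tie2 is also active in some blood cells.

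Detection used a floor. Negative control probe sets had been chosen for it beforehand, but none was among the probe sets analysed, and the fallback fixed in advance was used, namely the 40th percentile of each array. That floor fixes the share of probe sets above it, so only differences between lists can be read from it. A floor at the 90th percentile of the tissue-foreign genes on design A was planned as an alternative. A gene counted as above a floor when at least 1 of its probe sets exceeded it on all 3 arrays, and lists were compared with the other named genes of design A by Fisher's exact test. A gene with more probe sets could pass more easily, and lists were not matched on the number of probe sets. Shifts of a list in 1 replicate were measured on log2 intensities centred on the median of each array, against random lists matched on design and on 10 bins of mean signal.

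The genes named were fixed by rule. They are 14 preset genes, the 3 genes with the highest and the 1 with the lowest mean percentile of each list other than the tissue-foreign one (taken on design A where the gene is there), and the 3 genes per design with the largest range between replicates. Other list members named as examples were chosen after their values were seen. Of 98 list genes named by the rule, 20 had several probe sets on the design used and 11 of these had probe sets on both sides of the floor.

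Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The tests were tried on simulated data made from the real positions of 15964 genes. Raised by 20 percentile points, a list of 20 genes was called at an unadjusted p under 0.05 in 97.5% of 40 simulated lists by the position test and in 80.0% by the contrast between 2 lists. A list raised by 10 points was called in 52.5% and 37.5%, and an unchanged list in 5.0% and 7.5%. For unchanged lists of 12 genes, the position test called 12.5% and the contrast 5.0% of 40 lists. The test for a shift in 1 replicate was simulated on 8251 genes of design A, with noise drawn separately for each probe set. At an unadjusted p under 0.05, it called 62.5% of 20-gene lists raised by 0.1 on the log2 scale and 0% of unchanged ones. The real test was adjusted over 159 combinations of list and array, some with only 3 genes, so these shares do not give its power. Alternatives left out each replicate, used the strongest probe set per gene, mean log2 signal, design A alone, plain probe sets alone or a filter at the floor, and changed the floor, the normalization and the offset before logarithms.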

Results

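Cells sorted as endothelial by Tie2-driven GFP were profiled from the retinas of mouse pups at postnatal day 8, after injections of an antibody against PDGFRb from day 0 to day 7. PDGFRb is the receptor through which pericytes, the mural cells of capillaries, are recruited by endothelial PDGF-B, and the series describes these retinas as lacking pericyte coverage. All 9 arrays carried cells from antibody-treated animals, with 3 replicates on each of the array designs A, B and C. The effect of the antibody itself therefore cannot be read from these arrays. What they show is how high the signal of genes lay within the arrays, how closely the replicates agreed, and which gene lists stood out from the other genes of the same arrays.

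Replicates lay close together. The median intensity was between 43.6 and 44.3 on the 3 arrays of design A (12422 probe sets), between 42.9 and 44.5 on design B (12411 probe sets) and between 32.3 and 32.9 on design C (11868 probe sets). The scaling of the arrays is not known, so close medians may come from it and do not measure agreement. Log2 intensities of replicate arrays correlated across probe sets with r between 0.984 and 0.987 on design A, between 0.982 and 0.985 on design B and between 0.981 and 0.984 on design C. The median probe set had an SD over the 3 replicates of 0.13 on the log2 scale on design A, 0.13 on design B and 0.14 on design C. Few probe sets above the floor spread by more than 1 log2 unit between replicates, namely 81 of 7034 on design A, 81 of 6999 on design B and 60 of 6693 on design C. With 50 added to each intensity before logarithms, these counts were 31, 36 and 12. Without replicate 2 they were 15, 16 and 13, and without replicate 1 they were 39, 33 and 22. Without replicate 3, the count on design B was 53. A range over 2 arrays cannot exceed that over 3, so counts without a replicate could not rise. Among probe sets above the floor with 1 gene symbol, the widest spread belonged to Malat1, a nuclear long noncoding RNA. Its probe set on design B read 841, 209 and 56.2 in the 3 replicates. Acvr1b, an activin receptor, read 1964, 558 and 1442 on design B, and Urod, an enzyme of haem synthesis, read 545, 90.6 and 593 on design A. Ranges were 2.11 log2 units for Klk1b8 and 2.01 for Ino80e on design A, 1.80 for Rbm5 on design B, and 2.17 for Zkscan14, 1.89 for Dclk1 and 1.73 for Gm2449 on design C. The probe sets of Urod, Klk1b8 and Dclk1 are marked by their names as shared or reduced.

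Endothelial genes stood above the other genes of the arrays. The 23 measured pan-endothelial genes stood at a mean percentile of 73.99 ± 0.35 (SD, n = 3 replicates), against 43.2 to 60.8 for 95% of random lists (permutation test, adjusted p = 0.00080, which rests on the smallest p that 10000 random lists can give, 0.0001). Eng, an endothelial TGF-beta co-receptor, lay at percentile 99.7 ± 0.065, the VEGF receptor Kdr at 99.3 ± 0.27, the tight junction claudin Cldn5 at 99.2 ± 0.33 and the adherens junction cadherin Cdh5 at 98.8 ± 0.49 (SD, n = 3 each). Tek, which encodes Tie2 and whose promoter drove the GFP used in the sort, lay at 92.6 ± 0.26. Of the 17 pan-endothelial genes on design A, 15 exceeded the floor (Fisher's exact test, adjusted p = 0.15) and 14 exceeded the 90th percentile of the tissue-foreign genes (adjusted p = 0.00077). The adhesion molecule Pecam1 lay at percentile 52.4 ± 2.5 and the sphingosine receptor S1pr1 at 14.7 ± 2.2 and, on design C, 33.6 ± 7.6. Different probe sets of the same gene could differ widely. Kdr lay at 49.6 ± 1.6 on design C and the transcription factor gene Sox18 at 87.7 ± 1.5 on design A and 9.71 ± 3.6 on design C. Positions also depend on the probes (design A unless another is named), so the order of genes within a list is not an order of their transcript levels, and a low position does not show that a transcript was absent.

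**Figure D1:**
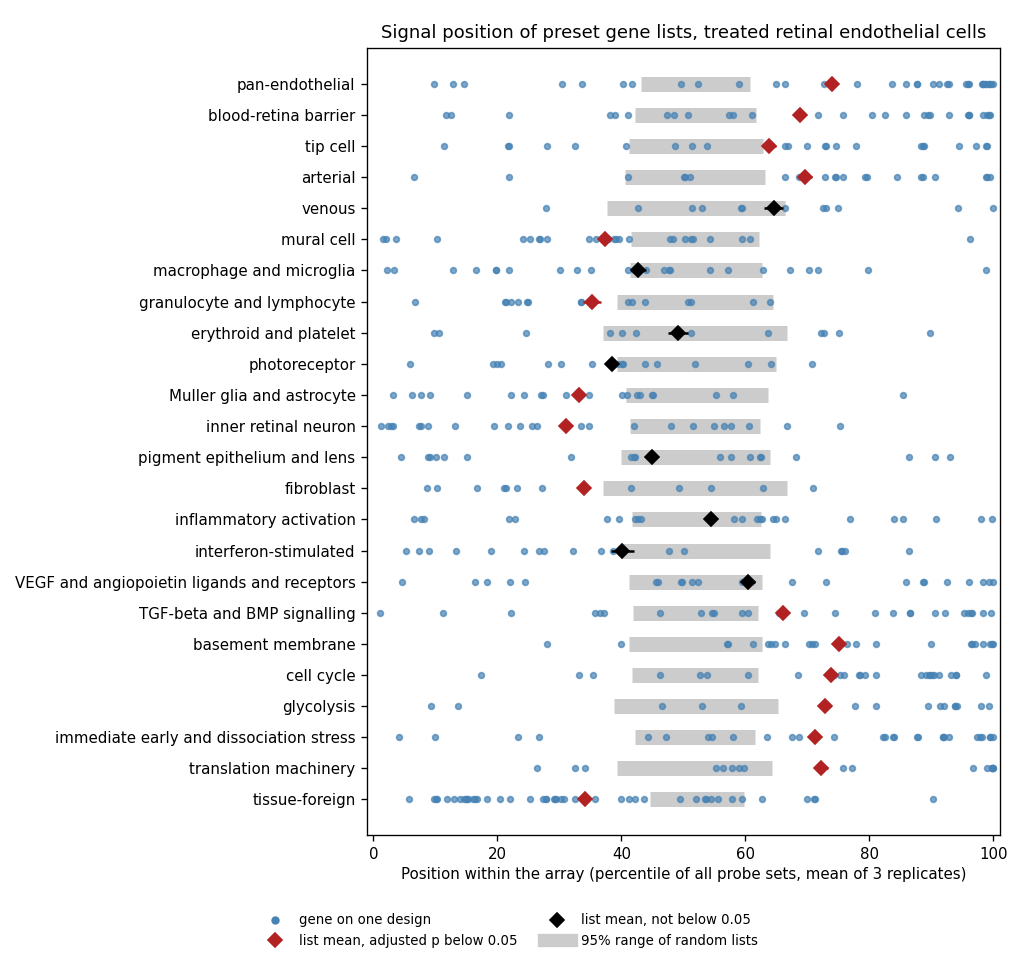
Position of the 24 preset gene lists within the arrays (x axis, percentile of all probe sets of an array, mean of 3 replicates). Blue points are genes on one design, diamonds are list means with the SD over 3 replicates, red where the adjusted p of the permutation test was below 0.05, and grey bars span 95% of random lists. The pan-endothelial mean at 73.99 lies above its grey bar, and the mural cell mean at 37.4 lies below its own.

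Genes of the blood-retina barrier also stood above other genes, at a mean percentile of 68.9 ± 0.78 (SD, n = 3; 20 genes; permutation test, adjusted p = 0.0027). Besides Cldn5, the Wnt-responsive gene Apcdd1 lay at 96.1 ± 1.3. The efflux transporter Abcg2 lay at percentile 98.3 ± 0.15 on design A, but at 12.5 ± 3.6 on design B and 21.9 ± 1.9 on design C, below the floor on both. The glucose transporter Slc2a1 lay at 89.4 ± 1.6, the lipid transporter Mfsd2a at 89.8 ± 3.8 on design B and 61.0 ± 2.7 on design C, and the efflux pump Abcb1a at 80.5 ± 2.1. The monocarboxylate transporter Slc16a1 lay at 11.7 ± 1.4. Of the 17 barrier genes on design A, 15 exceeded the floor (Fisher's exact test, adjusted p = 0.15) and 14 the tissue-foreign threshold (adjusted p = 0.00077).

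Arterial genes stood at a mean percentile of 69.6 ± 1.1 (SD, n = 3; 16 genes; permutation test, adjusted p = 0.0031), with the semaphorin Sema3g at 98.9 ± 0.045 on design B and the arterial ephrin Efnb2 at 98.8 ± 0.36. Nrp1, a VEGF co-receptor, lay at 88.6 ± 0.15. The chemokine receptor Cxcr4 lay at 21.9 ± 5.7. Restricted to probe sets above the floor, the arterial list was no longer apart from random lists (permutation test, adjusted p = 0.36). Venous genes had a mean of 64.6 ± 1.5 (SD, n = 3; 10 genes) and did not pass the permutation test (adjusted p = 0.11), although the amino acid transporter Slc38a5 lay at 94.3 ± 3.5 and the venous transcription factor gene Nr2f2 at 27.8 ± 2.8, with probe sets on both sides of the floor. Nr2f2 lay at 59.3 ± 3.8 on design B and 74.9 ± 6.7 on design C. The apelin receptor Aplnr lay at 72.5 ± 0.67 on design A and 99.9 ± 0.041 on design B, and the VEGF-C co-receptor Nrp2 at 73.0 ± 5.1 on design B. With the strongest probe set of each gene, the venous list did pass (permutation test, adjusted p = 0.046).

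Tip cell genes, which mark the leading cells of sprouts, had a mean percentile of 63.8 ± 1.1 (SD, n = 3; 17 genes; permutation test, adjusted p = 0.045). Esm1, a secreted proteoglycan of sprouting endothelium, lay at 98.8 ± 0.56 on design B, the adhesion molecule gene Mcam at 94.4 ± 0.54 and Angpt2, the destabilising Tie2 ligand, at 88.8 ± 0.81. The ectonucleotidase gene Nt5e lay at 21.7 ± 3.5. Pdgfb, the ligand of the blocked receptor, lay at 48.6 ± 2.5 on design A and at 97.2 ± 0.54 on design B. The tip cell call did not hold without replicate 1 (permutation test, adjusted p = 0.052), without replicate 2 (adjusted p = 0.051), on design A alone (adjusted p = 0.36) or with the strongest probe set per gene (adjusted p = 0.069).

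Mural cell genes stood below other genes. Pdgfrb, the antibody's target, read 33.6 ± 7.6 (SD, n = 3), at percentile 38.8 ± 9.1. It lay near the floor, with 34.4, 25.5 and 40.7 in the 3 replicates against floors of 33.5, 34.2 and 34.9, and so exceeded it on 2 of 3 arrays. The 18 measured mural genes had a mean percentile of 37.4 ± 0.41 (SD, n = 3 replicates; permutation test, adjusted p = 0.011), beside 34.2 ± 0.25 for the 37 tissue-foreign genes. On design A, 6 of 14 mural genes exceeded the floor (Fisher's exact test, adjusted p = 0.17) and 1, Mylk, exceeded the tissue-foreign threshold (adjusted p = 0.062). The share above the floor was 42.9% for mural genes and 41.7% for tissue-foreign genes (15 of 36). Exceeding the floor therefore does not show that a mural transcript was present. Mylk, a myosin light chain kinase, lay at percentile 96.2 ± 2.6 on design A, but its 3 probe sets on design B averaged 48.4 ± 2.0. The potassium channel Kcnj8 lay at 59.5 ± 7.7, the actin-binding Tagln at 54.2 ± 3.7 and the channel subunit Abcc9 at 3.62 ± 0.41 and, on design B, 26.9 ± 0.78. On design A alone the mural mean was 39.7 and the list did not pass (permutation test, adjusted p = 0.11).

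The pan-endothelial list lay above every other cell type list tested. Its mean exceeded that of mural cells by 36.6 percentile points (permutation test, adjusted p = 3.3e-05), of inner retinal neurons by 42.9 (adjusted p = 2.5e-05), of Muller glia and astrocytes by 40.8 (adjusted p = 2.5e-05), of fibroblasts by 40.05 (adjusted p = 0.00054) and of photoreceptors by 35.5 (adjusted p = 3.3e-05). The gap to macrophages and microglia was 31.2 points (permutation test, adjusted p = 0.0018) and to granulocytes and lymphocytes 38.7 points (adjusted p = 2.5e-05). It was 29.1 points to pigment epithelium and lens (permutation test, adjusted p = 0.0031) and 24.8 points to erythroid cells and platelets (adjusted p = 0.016), and these last gaps did not pass among probe sets above the floor (adjusted p = 0.16 and 0.17). The tissue-foreign list lay 39.8 points below the pan-endothelial one (permutation test, adjusted p = 2.5e-05). Among probe sets above the floor, the gaps were 18.3 points to neurons, 19.8 to glia, 22.6 to fibroblasts, 24.6 to tissue-foreign genes and 12.6 to pigment epithelium and lens.

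Against random lists, neurons (mean percentile 31.0), Muller glia and astrocytes (33.2), fibroblasts (33.9) and granulocytes and lymphocytes (35.3) were below other genes by the permutation test, with adjusted p of 0.00080, 0.0031, 0.028 and 0.015. Among probe sets above the floor, neurons, glia and fibroblasts did not pass (permutation test, adjusted p = 0.73, 0.61 and 0.40), whereas mural genes and granulocytes and lymphocytes did (adjusted p = 0.0020 and 0.036). The glial call was also lost on design A alone (permutation test, adjusted p = 0.10) and the fibroblast one with the strongest probe set per gene (adjusted p = 0.27). Photoreceptor genes (38.5, permutation test, adjusted p = 0.054), macrophage and microglial genes (42.7, adjusted p = 0.11), lens and pigment genes (44.9, adjusted p = 0.27) and erythroid and platelet genes (49.2, adjusted p = 0.73) did not pass. Macrophage and microglial genes did pass as lower on design A alone (permutation test, adjusted p = 0.043) and with plain probe sets alone (adjusted p = 0.034). Photoreceptor genes did without replicate 3 (permutation test, adjusted p = 0.046) and among probe sets above the floor (adjusted p = 0.048).

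Members of these lists differed widely in position. Laptm5, a lysosomal membrane protein of blood cells, lay at percentile 79.8 ± 8.4 on design A and 98.8 ± 0.88 on design C, whereas Lyz2, the lysozyme of macrophages, lay at 12.8 ± 2.2 and the microglial receptor P2ry12 at 2.12 ± 0.32 on design C. The P2ry12 value rests on 1 probe set, which its name marks as shared or reduced. Fcgr3 lay at 67.1 ± 0.85 and the growth factor receptor Csf1r at 62.8 ± 3.2, with probe sets on both sides of the floor. Carbonic anhydrase Car2, in the glial list, lay at 85.4 ± 2.8, and the lens crystallin Cryaa at 90.6 ± 2.2 on design A and 57.7 ± 1.5 on design C. The photoreceptor transcription factor gene Crx lay at 70.8 ± 1.3 and the alpha globin gene Hba-a1, which shares sequence with its near-identical copy, at 75.1 ± 1.3. The calcium-binding protein gene Calb2 lay at 75.2 ± 4.7 and the synaptic vesicle gene Syt1 at 1.18 ± 0.34 on design A and 51.6 ± 4.7 on design B (SD, n = 3 each).

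Other members of these lists also lay on both sides of the floor. In the neuronal list, Pcp2, a gene of bipolar cells, was the mean (56.5 ± 1.2) of probe sets at percentiles 14.3 and 98.8, and the neuronal tubulin Tubb3 (57.7 ± 2.3) of probe sets at 37.6 and 77.7. In the fibroblast list, the matrix protein gene Fbln2 lay at 70.9 ± 1.3 on design A and 10.2 ± 2.0 on design C, and the proteoglycan gene Lum at 8.63 ± 1.9. Fbln1 (54.5 ± 2.2) and the type I collagen chain Col1a2 (49.3 ± 4.9) had probe sets from 38.6 to 77.1 and from 22.4 to 76.2. The neutrophil genes Camp and Prtn3 lay at 63.9 ± 0.93 and 61.3 ± 1.5 and the B cell receptor gene Cd79a at 51.3 ± 2.6. Of 16 probe sets for the immunoglobulin heavy chain Ighm (21.3 ± 0.25), 1 exceeded the floor. The platelet genes Gp9, Itga2b and Ppbp lay at 72.2 ± 1.1 on design A, 72.6 ± 2.0 on design C and 9.81 ± 3.5 on design B. The photoreceptor genes Sag, Opn1mw and Cnga1 lay at 64.1 ± 7.6, 60.4 ± 7.5 and 5.83 ± 1.6. In the glial list, Clu lay at 44.9 ± 1.4, with 1 of 2 probe sets above the floor, the potassium channel Kcnj10 at 7.74 ± 1.1 on design B, and the carbonic anhydrase Car14 at 43.0 ± 6.6 on design A and 55.3 ± 4.2 on design B. The lens membrane protein gene Lim2 lay at 86.3 ± 5.3 on design B and the pigment gene Tyr at 9.12 ± 2.4. Dct, another pigment gene, lay at 68.2 ± 3.5, 8.82 ± 2.3 and 60.7 ± 5.0 on designs A, B and C (SD, n = 3 each).

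Genes of inflammatory activation were not apart from other genes as a list. Their mean percentile was 54.5 ± 0.51 (SD, n = 3; 19 genes; permutation test, adjusted p = 0.69). Within the list, the neutrophil chemokine gene Cxcl1 lay at percentile 97.99 ± 0.065, the transcription factor gene Irf1 at 90.7 ± 1.4 and Csf1, the growth factor of macrophages, at 85.4 ± 0.79. The leukocyte adhesion molecule Icam1 lay at 66.4 ± 6.1 and the monocyte chemokine gene Ccl2 at 64.4 ± 5.8. Vcam1 averaged 59.5 ± 3.2 over 3 probe sets that ranged from percentile 36.9 to 95.8, on both sides of the floor. E-selectin, Sele, lay at 21.9 ± 8.0, the cytokine gene Il6 at 7.61 ± 1.7 and the chemokine gene Ccl7 at 6.52 ± 0.37. On design A, 13 of 19 genes exceeded the floor and 6 the tissue-foreign threshold. Interferon-stimulated genes had a mean of 40.2 ± 1.9 (SD, n = 3; 14 genes) and did not pass the permutation test (adjusted p = 0.070). The immunoproteasome subunits Psmb8 and Psmb9 lay at 86.3 ± 0.98 and 76.0 ± 2.1, Ifi35 at 75.4 ± 1.9, and the antiviral Mx1 at 5.30 ± 0.13. On design A alone and with the strongest probe set per gene, the interferon list passed as lower than other genes (permutation test, adjusted p = 0.043 in both).

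**Figure D2:**
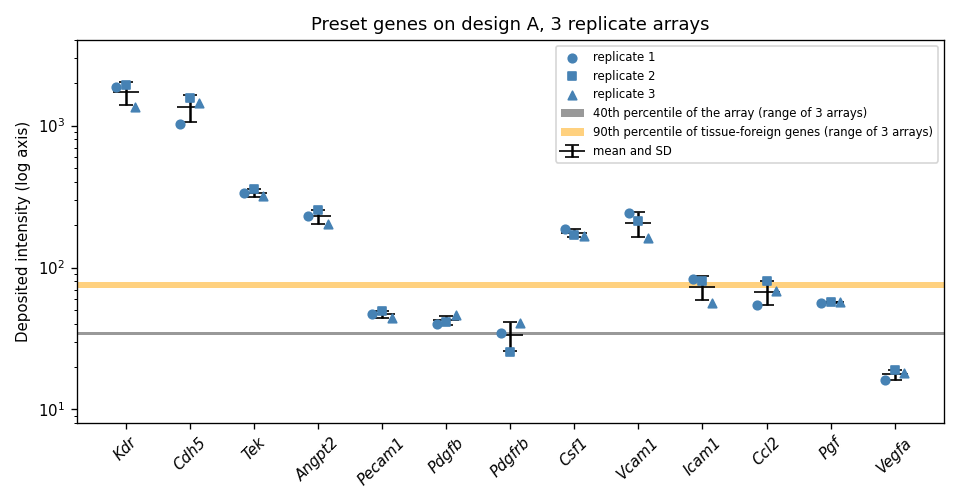
Deposited intensity (y axis, log scale) of 13 preset genes on design A in the 3 replicate arrays, with the mean and SD. The grey band is the 40th percentile of the arrays and the orange band the 90th percentile of tissue-foreign genes. Kdr, Cdh5, Tek, Angpt2 and Csf1, with 1 probe set each, lie above the orange band in all replicates. Vcam1 also lies above it, but is drawn as the mean of 3 probe sets, of which only 1 exceeds that threshold. Pdgfrb, at 33.6 ± 7.6, straddles the grey band.

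Ligands and receptors of the VEGF and angiopoietin systems had a mean percentile of 60.5 ± 1.1 (SD, n = 3; 16 genes) and did not pass the permutation test (adjusted p = 0.13), but passed on mean log2 signal (adjusted p = 0.016). The VEGF receptor gene Flt1 lay at 96.1 ± 0.045 on design A. The ligand gene Vegfa lay at 16.4 ± 1.8 on design A, 4.63 ± 2.8 on design B and 67.6 ± 3.6 on design C, and the VEGF receptor 1 ligand gene Pgf at 59.5 ± 0.28. Foxo1, a transcription factor downstream of Tie2 signalling, averaged 52.4 ± 0.69 on design B over 3 probe sets between percentiles 20.01 and 86.6, on both sides of the floor.

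Basement membrane genes were high, at a mean percentile of 75.1 ± 0.78 (SD, n = 3; 14 genes; permutation test, adjusted p = 0.00080). The type IV collagen chains Col4a1 and Col4a2 lay at 99.9 ± 0.026 and 99.4 ± 0.11, the matricellular Sparc at 98.3 ± 0.25 (39.9 ± 9.2 on design B) and the laminin chain Lama5 at 57.1 ± 3.4. All 14 exceeded the floor on design A, against 66.2% of other named genes (Fisher's exact test, adjusted p = 0.031), and 9 exceeded the tissue-foreign threshold (adjusted p = 0.099). The first call was lost without replicate 1 (exact test, adjusted p = 0.059), without replicate 3 (adjusted p = 0.058) and when 2 of 3 arrays sufficed (adjusted p = 0.064). Genes of TGF-beta and BMP signalling had a mean of 66.1 ± 0.78 (SD, n = 3; 16 genes; permutation test, adjusted p = 0.011). Beside Eng, the BMP-responsive Smad1 lay at 96.5 ± 0.11 and the inhibitor of differentiation Id2 at 86.5 ± 1.9, and the receptor Tgfbr1 at 11.2 ± 2.4 on design A and 92.2 ± 1.7 on design B. On design A alone this list did not pass (permutation test, adjusted p = 0.24). Among probe sets above the floor, both lists passed at a smaller distance from random lists, basement membrane genes at 81.7 against 71.8 and TGF-beta and BMP genes at 80.6 against 71.6.

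Proliferation genes stood above other genes. The 22 measured cell cycle genes had a mean percentile of 73.8 ± 0.98 (SD, n = 3; permutation test, adjusted p = 0.00080). The replication clamp Pcna lay at 98.8 ± 0.15, the mitotic kinases Aurkb and Cdk1 at 93.9 ± 1.1 and 93.9 ± 0.96, and the proliferation antigen Mki67 at 89.8 ± 2.6. Thymidylate synthase, Tyms, lay at 17.3 ± 4.8 on design C, by 1 probe set that its name marks as shared or reduced. On design A, 18 of 20 genes exceeded the floor (Fisher's exact test, adjusted p = 0.13) and 15 the tissue-foreign threshold (adjusted p = 0.0031). Glycolysis genes had a mean of 72.8 ± 0.91 (SD, n = 3; 12 genes; permutation test, adjusted p = 0.0041), with the lactate dehydrogenase gene Ldha at 99.3 ± 0.086, Pgk1 at 98.02 ± 0.15 (13.6 ± 0.88 on design B) and Aldoa at 94.1 ± 0.63, and the hexokinase gene Hk2 at 9.30 ± 5.5. Among probe sets above the floor, cell cycle genes stood at 82.9 against 71.6 for random lists and glycolysis genes at 83.5 against 71.4. The translation machinery had a mean of 72.3 ± 1.0 (SD, n = 3; 12 genes; permutation test, adjusted p = 0.0030). Rps3, Eef1a1 and Rps18 lay at 99.9 ± 0.017, 99.9 ± 0.026 and 99.8 ± 0.041, and Rps14 at 32.5 ± 3.9. Rps3 lay at 56.5 ± 2.5 on design C.

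Immediate early and heat shock genes, which respond within minutes to hours to handling and stress of tissue, also stood above other genes. Their mean percentile was 71.2 ± 0.20 (SD, n = 3; 20 genes; permutation test, adjusted p = 0.00080). The inducible chaperones Hspa1a and Hspa1b, whose near-identical transcripts the probe sets could share, lay at 99.5 ± 0.20 and 99.4 ± 0.12, and the transcription factor gene Klf6 at 98.1 ± 0.29. The AP-1 genes Fosb, Fos and Jun lay at 92.0 ± 0.13, 87.7 ± 3.2 and 87.8 ± 1.5, and Jun at 9.92 ± 1.8 on design C. Egr1, at 44.3 ± 2.1, was the mean of 2 probe sets at percentiles 3.02 and 85.7, on both sides of the floor. All 20 genes exceeded the floor on design A, against 66.2% of other named genes (Fisher's exact test, adjusted p = 0.011), and 19 exceeded the tissue-foreign threshold (adjusted p = 8.1e-07). With plain probe sets alone, the mean was 83.03 against 53.2 for random lists. The cells had passed through several enzymatic incubations before sorting. No cells without these incubations were measured, so whether they raised these genes was not tested.

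No list passed the test for a shift in 1 replicate. Of 159 combinations of list and array, none passed the permutation test against matched random lists after adjustment, and 12 had an unadjusted p below 0.05. How large a shift would have passed after adjustment was not simulated. The largest mean deviation of a list from the mean of its 3 replicates was 0.19 on the log2 scale, for 4 basement membrane genes in replicate 1 of design B (permutation test, adjusted p = 0.39). The smallest p belonged to cell cycle genes in replicate 1 of design A, with a mean log2 deviation of 0.13 (permutation test, p = 0.0011, adjusted p = 0.17). Mural genes in replicate 2 of design A had a mean log2 deviation of -0.12 from their mean over replicates (permutation test, adjusted p = 0.19). In replicate 2 of designs B and C the mural deviation had the opposite sign, at 0.061 and 0.087. Macrophage genes had adjusted p of 0.49 or more by the permutation test on all arrays tested.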

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

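The comparison of probe set pairs on 1 array and the tests over other matchings of array numbers were chosen after the correlations between designs were seen, and the other tests of this part were planned. No paired analysis was possible because all 9 arrays belong to 1 condition. Deviations of genes on 2 designs correlated between same-numbered arrays with r from 0.0218 to 0.10 (mean 0.059; 0.083 for genes above the floor). All 9 such values were above 0, against 3 of the 18 between other numbers, whose mean of -0.030 follows from centring. An array correlated best with its own number in 17 of 18 comparisons (14 of 18 above the floor). Of the 36 ways to match numbers across designs, the labels' gave the highest mean (one-sided exact permutation test, p = 0.028, the smallest possible; next 0.0483), a hint from the data that equal numbers share a source. Since the test was chosen after these correlations were seen, its p restates them and adds no separate support. The planned bound of 0.1 was too strict, since probe sets of a gene on 1 array, which share their RNA, reached only -0.019 to 0.083 (mean 0.029). Shared RNA and shared processing cannot be told apart, because both would follow the number. Other matchings widened the SD of 7 of 24 list means by over 1.5 times, to at most 2.09. The planned settings with control probe sets were not run, since none was among the probe sets analysed, and the planned 40th percentile became the floor itself. Over the alternatives, list positions kept direction and side of the threshold 169 times, lost a call 12 times, gained one 8 times and reversed 3 times. Contrasts kept both 78 times and detection 106 times. Lists above random ones numbered 8 to 11 and lists below 4 to 7. With the strongest probe set per gene, tip cell (67.7, permutation test, adjusted p = 0.069) and fibroblast genes (46.9) lost their call, and venous (73.0) and interferon genes (42.1) gained one. Mean log2 signal gave the VEGF list a call (1.08, random lists 0.26). Among probe sets above the floor, mural (56.7), granulocyte (55.9) and tissue-foreign genes (62.8) kept their call below random lists, arterial (76.1), glial (67.6), neuronal (69.1) and fibroblast (64.8) positions and the gaps to erythroid (16.6) and lens genes (12.6) lost their call, photoreceptor genes gained one (59.1), and lens (74.8) and interferon genes (73.6) reversed without a call. On design A alone, tip cell (59.7), mural (39.7), glial (36.9) and TGF-beta genes (60.7) lost it, and macrophage (39.2) and interferon genes (35.9) gained it. With plain probe sets, macrophage genes (39.7) gained it and inflammatory genes (52.9) reversed without a call. The tissue-foreign threshold left 3540 probe sets on design A. Detection there gained a call for endothelial and barrier (82.4% each), cell cycle and glycolysis (75% each), translation (80.0%) and granulocyte genes (0%), kept it for immediate early genes (95%) and, by construction, tissue-foreign ones (11.1%), lost it for basement membrane (64.3%) and reversed without one for inflammatory genes (31.6%). With 2 of 3 arrays sufficing, basement membrane (100%, Fisher's exact test, adjusted p = 0.064) lost its call and lens genes (75%) reversed without one. Leaving out each replicate gave 63.4 to 64.4 for tip cell genes, lost without replicates 1 and 2, and 38.1 to 38.7 for photoreceptor genes, called without replicate 3. Detection was 100 to 100% for basement membrane, lost without replicates 1 and 3, 90 to 95% for cell cycle and 30.8 to 38.5% for interferon genes, both called without replicate 2. Lists above random ones then numbered 9 to 10 and lists below 6 to 7. Median r was 0.984 to 0.987, 0.982 to 0.985 and 0.981 to 0.984 on designs A, B and C, and probe sets with a wide range numbered 15 to 69, 16 to 53 and 13 to 45, fewest without replicate 2. These ranges span 2 arrays, so the counts of such probe sets could not rise. An offset of 50 gave r of 0.989, 0.987 and 0.988 and 31, 36 and 12 such probe sets, and probe sets above the floor alone gave r of 0.981, 0.975 and 0.978. The cause of these differences was not tested. Signal near the floor limits what low positions show.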

Other observations

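The 7 gene lists described first, the tests on Mylk and Laptm5 and the test on plain probe sets of design C alone were chosen after the data were seen.

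Genes of oxidative phosphorylation stood above other genes, at a mean percentile of 79.3 ± 0.58 (SD, n = 3; 13 genes; permutation test, adjusted p = 0.00070 over 7 lists). The ATP synthase subunit Atp5a1 lay at 99.8 ± 0.093, the complex I subunit Ndufv1 at 96.1 ± 0.85 and the complex III subunit Uqcrc2 at 94.2 ± 0.19, while Cox5a lay at 98.3 ± 0.17 on design C and 26.7 ± 3.3 on design A. Genes of caveolae, the membrane pits through which endothelium carries cargo, stood at 73.4 ± 0.82 (SD, n = 3; 7 genes; permutation test, adjusted p = 0.038). Ehd2 lay at 98.5 ± 0.27 on design C, Cavin3 at 96.5 ± 0.42 on design A and 9.74 ± 1.8 on design C, Cav2 at 89.1 ± 0.25 on design B and Cav1 at 73.9 ± 3.6. Plvap, a marker of fenestrated and immature vessels, lay at 51.1 ± 0.98 on design B.

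Integrins (60.6, permutation test, adjusted p = 0.29), Eph receptors and ephrins (51.3, adjusted p = 0.93), semaphorins, plexins and netrins (40.1, adjusted p = 0.10), lymphatic endothelial genes (33.0, adjusted p = 0.14) and genes of fatty acid handling (44.0, adjusted p = 0.46) did not pass. The integrin genes Itgb1 and Itga6 lay at 96.7 ± 0.022 and 91.5 ± 0.95 and the semaphorin receptor Plxnd1 at 96.9 ± 0.28. The lymphatic transcription factor gene Prox1 lay at 28.7 ± 1.8. In fatty acid handling, Fabp4 lay at 7.73 ± 1.2 and Cpt1a at 88.9 ± 1.4.

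Some endothelial genes had low signal, Pecam1 lying 21.6 points below the mean of its list. Probe sets of 1 gene on 1 design differed by at least that much in 56.7% of 9860 pairs, with a median difference of 26.03 points against 29.3 for random pairs, so probe set performance may account for such low positions. Disagreement remained among plain pairs, which hold no probe set marked by its name as shared or reduced. Plain pairs correlated at most at 0.197 across genes, so shared or reduced probe sets were not the only source of the disagreement. The median difference across genes was 25.96 points for plain pairs on design A, 25.12 on design B and 21.96 on design C. For all pairs it was 25.42, 25.5 and 25.07. How much shared or reduced probe sets added was not tested. Partners of probe sets in the upper 10% had a median position of at most 63.2 on any design (95% bootstrap interval 57.6 to 70.5). Absent transcripts therefore did not account for the disagreement of such pairs, if the high signal came from the gene itself. Pairs without a probe set in the upper 10% were not tested, so absent transcripts stay open for them. They also stay open for plain pairs on design C, where that median was 73.3 (65.9 to 82.8; 67 partners). Bias of amplified RNA toward transcript ends stays open, as does a truly low level, and no biological explanation was tested.

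Mylk stood 4.51 ± 0.66 log2 units above the tissue-foreign genes on design A (SD, n = 3). The other 13 mural genes stood 0.0503 above them (95% bootstrap interval -0.48 to 0.51). Laptm5 stood 2.25 ± 0.58 above, and the other 19 macrophage and microglial genes 0.0696 (-0.44 to 0.58). These differences set probe sets of different genes against each other, and 15 of the 36 tissue-foreign genes themselves exceeded the floor. The differences therefore decide nothing about residual mural cells or macrophages. The Laptm5 probe sets lay at percentiles 79.4 and 80.3 on design A and 98.8 on design C, and Mylk lay at 48.4 ± 2.0 on design B. Every Laptm5 probe set read lowest in replicate 1, with 83.7, 156 and 156 and with 79.3, 184 and 168 on design A. On design C the readings were 486, 810 and 787. Csf1r, of the same list, went the other way, with means of 187, 80.1 and 137 on design A. The macrophage list as a whole passed no test for a shift. Residual cells, expression in the sorted cells and cross-hybridisation stay open for Mylk and Laptm5. The sorted cells could include blood cells, since Tie2 is also active in some of these.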
